A study of Mus musculus with 36 samples.

How the data were processed

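Total RNA from 3T3-L1 cells was sequenced in 12 RNA-seq libraries, 3 for each combination of genotype label (WT or Zfp217 knockout) and day (0 or 2 of the adipogenic cocktail). The libraries were made with a NEBNext Ultra RNA kit per the labels. The series also holds 24 MeRIP samples, 12 immunoprecipitated and 12 input, which were not analysed here. The submitters' processing notes name CASAVA, FastQC, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1, BWA 0.7.12 and MACS2 2.1.0 and the genome build mm10, without giving the role of each. The gene annotation, the strand setting and the formula of the expression values are not given in the sources used here.

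The deposited expression table holds FPKM values (fragments per kilobase of gene length, scaled to sequencing depth) for 52505 genes in the 12 libraries, as the authors computed them. Of the identifiers 51633 have a symbol. The table was checked for its unit: 30916 genes were above 0 in at least 1 library and 21589 were listed at 0 in every library. In each of the 30916 the values were whole multiples of a single step per gene (tolerance 0.001 of a read), from which read numbers were recovered. For a gene above 0 in 1 or very few libraries this check could hardly fail, and reads that share a factor come out divided by it. The gene lengths implied were whole in 99.99% of genes above 0 in all libraries (tolerance 0.05 bases). Recovery for the other genes has no such check. The recovered totals were 18073258 to 23114994 reads per library. For genes with at least 100 reads in a pair of libraries of a group, the median chi-square between them was 1.38 to 2.09 times that of counting noise alone. The mean per gene was 2.91 to 22.38, where counting noise gives 1, so some genes differed far more. It was highest for WT day 0 replicates 2 and 3. The 12 columns were matched to the samples by genotype, day and replicate number in their names.

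Values were analysed as log2(FPKM + 1), with a pseudocount of 1, for the 12961 genes with a mean of at least 1 FPKM over the 12 libraries. A model with a mean for each of the 4 groups was fitted to each gene with limma 3.58.1 in R 4.3.3, with a variance trend and 8 residual degrees of freedom. The comparisons were KO with WT at each day, day 2 with day 0 in each genotype, and the interaction. Tests were 2-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. For a gene listed at 0 in a group, the fitted change depends on the pseudocount and is no fold. A pair of groups of 3 was also compared by an exact permutation test for Zfp217 alone. No replicate block was used, since no label says that a number marks a shared culture. The deviations of same-numbered libraries had correlations across genes of -0.055 to 0.087, and 6 of 12 libraries correlated best with a library of their own number.

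Before the data were examined, the comparisons, tests, thresholds, 30 gene lists, most alternative settings and the rule for named genes were fixed. The rule names Zfp217, the 6 largest rises and 6 largest falls among genes that passed with no overlap between the groups (4 each for the KO response and the interaction, the latter with no rule on overlap), up to 4 members of each called list with the smallest adjusted p, and 12 genes of m6A and fat cell formation at both days. Predicted genes and clone names were left out. Other list members appear as examples, chosen after their values were seen. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, which compares a list with all other genes. Of the 30 lists, 28 had at least 2 tested members. In every called list the median, the mean and the test had the same sign. The lists cover m6A machinery, repressor partners of Zfp217, fat cell regulators, fat cell genes and lipid synthesis, cell cycle, matrix and contractile genes, Wnt, glucocorticoid, cyclic AMP, interferon, inflammatory, p53 and stress responses, respiratory chain, imprinted, ribosomal and histone genes, and markers of other cell types.

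The alternatives fixed then were a pseudocount of 0.1, no filter (30916 genes) or a mean of at least 5 FPKM (9692 genes), TPM, median-of-ratios and quantile scaling, no variance trend, only the libraries compared, a replicate block, each library left out in turn, a 2-fold minimum, camera with an estimated correlation, and fry. Chosen after seeing the data were voom on the recovered reads with precision weights and the treat test against a 1.5-fold difference. The fits were tested on simulated data with 50 genes at each of 4 sizes of change and 12260 unchanged genes. At day 0, 8% of genes changed 1.2-fold, 66% changed 1.5-fold, 90% changed 2-fold and 96% changed 4-fold were called, with 6 unchanged genes called. At day 2 the shares were 2%, 72%, 92% and 94%, with 10 unchanged genes called. The simulation had a dispersion of 0.005 and only 200 changed genes. In the real comparisons of KO with WT most genes passed, at a median SE of 0.056 in log2. The simulated shares therefore do not tell how often a small change is called in the real data.

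Positions are from the GRCm38.p6 annotation, the same build as mm10. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.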

Results

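RNA was sequenced from 3T3-L1 cells, a mouse fibroblast line that turns into fat cells when given an adipogenic cocktail. Cells labelled wild type (WT) and cells labelled as Zfp217 knockout (KO) were each sampled at day 0, before the cocktail, and at day 2 of treatment. The cocktail held dexamethasone, the phosphodiesterase inhibitor IBMX, insulin and indomethacin. The 12 libraries form 4 groups of n = 3, and the reads recovered for each came to between 18073258 and 23114994. All values below are FPKM as mean ± SD of the 3 libraries of a group, unless a log2 change with its standard error (SE) is given. Across genes, Pearson's r was 0.992 to 0.996 between libraries of a group and 0.786 to 0.92 between groups. The first principal component held 53.3% of the variance and the second 32.3%. No label says whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which can be purely technical. Nor do the labels say whether the KO cells are a single clone, so a difference between the genotypes can also be one between cultures of different history.

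A single library, WT day 0 replicate 3, stood apart from its group. In it 23 genes were at least 4-fold from the other libraries of the group, against 1 to 8 genes in each of the other 11 libraries. The mitochondrial ribosomal RNA mt-Rnr1 was at 264 FPKM in this library against 7.01 and 5.87 in the other WT day 0 libraries. The KO-labelled day 0 libraries held mt-Rnr1 at 379 to 396 FPKM, and the day 2 libraries of both genotypes at 13.5 to 19.9. Hsp90aa1, a heat shock chaperone gene, followed the same libraries, at 886 FPKM in WT day 0 replicate 3, 27.2 and 28.5 in the other WT day 0 libraries, 174 to 178 in KO day 0 and 4.7 to 17.7 at day 2. Both genes were picked here after their values were seen, and the ribosomal RNA difference goes along with every comparison that involves the KO day 0 group.

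**Figure D1:**
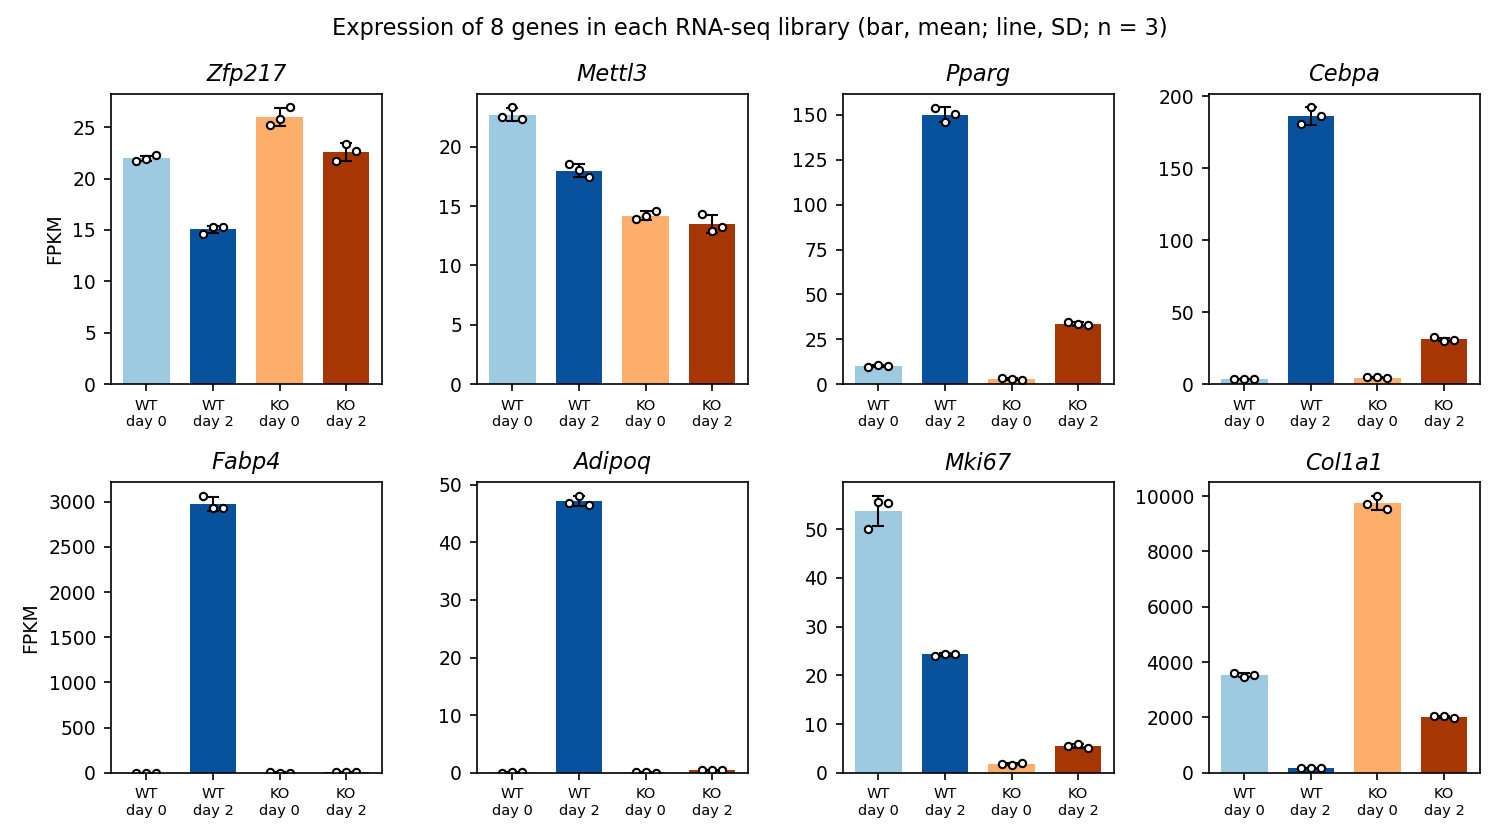
FPKM of 8 genes in the 4 groups on linear axes from 0, with bars at the group mean, lines for the SD and a point for each of the 12 libraries. Zfp217 is no lower in the libraries labelled knockout, at 25.97 ± 0.883 against 21.96 ± 0.279 FPKM at day 0 (SD, n = 3), while Fabp4 at day 2 is at 2970 FPKM in WT and 10.3 in KO.

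Zfp217 (ENSMUSG00000052056), a zinc finger transcription regulator, lies on chromosome 2 of GRCm38.p6 from 170108643 to 170151677. Its message was not lower in the libraries labelled knockout. At day 0 it was at 21.96 ± 0.279 in WT and 25.97 ± 0.883 in KO, a ratio of 1.18 (log2 change 0.23, SE 0.04, adjusted p = 7.58e-05). At day 2 it was at 15.06 ± 0.369 in WT and 22.59 ± 0.858 in KO, a ratio of 1.5 (log2 change 0.55, SE 0.04, adjusted p = 2.41e-08). All 3 libraries labelled KO were above all 3 WT libraries at each day. The 2-sided exact permutation p was 0.1 at both days, the smallest that 3 libraries against 3 can give. The message level thus goes against the label, and every direction given as KO against WT is a direction between libraries as labelled. A gene-level value cannot show a frameshift or the loss of an exon.

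The comparison of KO with WT at day 0 asks how the labelled knockout cells differ before the cocktail is added. Cell division genes were far lower in the KO-labelled cells. Ccnb1, the cyclin that drives entry into mitosis, was at 88.3 ± 1.65 in WT and 2.72 ± 0.0241 in KO, 32.4-fold lower, and the proliferation marker Mki67 went from 53.7 ± 3.1 to 1.81 ± 0.13. Interferon-stimulated genes were higher, with the tetherin gene Bst2 at 68.7 ± 3.65 in WT and 534 ± 7.59 in KO. The collagen gene Col3a1 was higher too, at 1080 ± 10 in WT and 7790 ± 33 in KO. Of 12961 genes tested, 10684 passed, 4958 higher and 5726 lower in KO, and 1345 and 1546 of these differed at least 2-fold. Which direction holds more genes depends on the setting, with 5930 higher and 5158 lower after TPM scaling, 5425 and 5237 after quantile normalization, 5479 and 5204 in the fit on recovered reads and 7115 and 6728 with no filter.

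The largest rises at day 0 were those of the apolipoprotein gene Apod (8.22 ± 0.567 to 565 ± 1.49, 68.7-fold), the serpin gene Serpinb7 (0.069 ± 0.0851 to 62.2 ± 1.6), the bicarbonate transporter gene Slc4a10 (0.296 ± 0.0935 to 55.2 ± 1.22), the growth factor gene Igf2 (0.917 ± 0.0527 to 71.8 ± 1.34, 78.3-fold), the osteocrin gene Ostn (0.257 ± 0.104 to 45.6 ± 1.34) and Enpp2 (1.37 ± 0.0557 to 77.3 ± 0.727), which encodes autotaxin. The largest falls were those of the lysosomal protease gene Ctsz (62.3 ± 2.3 to 0.0452 ± 0.017), the myosin light chain gene Myl9, and 4 genes of the cell cycle. Myl9 was at 41.3 ± 2.17 in WT and is listed at 0 in all 3 KO libraries. The cell cycle genes were Pimreg (107 ± 3.71 to 2.68 ± 0.501), Pclaf (69.9 ± 1.56 to 1.9 ± 0.194), Uhrf1 (96.5 ± 1.64 to 3.04 ± 0.234) and Ccnb1. The adjusted p of these 12 genes was at most 1.38e-13. That no library of KO overlapped with WT in any of them was asked for by the naming rule.

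Gene lists fixed before the data were examined gave the wider picture at day 0. All 24 mitotic genes tested were lower (median log2 change -3.95, adjusted p = 1.62e-11), among them Plk1 (77.6 ± 1.4 to 2.93 ± 0.38) and Aurkb (52.8 ± 1.7 to 1.43 ± 0.28), kinases of mitosis. All 26 DNA replication genes were lower (median -2.76, adjusted p = 1.02e-10), such as the helicase subunit gene Mcm5 (84 ± 0.96 to 4.01 ± 0.19). All 21 cholesterol synthesis genes were lower (median -2.49, adjusted p = 4.08e-10), such as Idi1 (286 ± 8 to 19.2 ± 0.98). All 26 interferon-stimulated genes were higher (median 2.41, adjusted p = 1.8e-10), such as Mx1 (0.929 ± 0.0455 to 17.7 ± 0.172, 19-fold), Oasl2 (11.7 ± 0.291 to 90.3 ± 1.9) and Oas2 (1.48 ± 0.0601 to 20.5 ± 0.683). Of 14 contractile genes, 13 were lower and 1 higher (median -1.19, adjusted p = 1.82e-04). Among them the smooth muscle actin gene Acta2 went from 541 ± 8.3 to 74 ± 1.21 and Ccn1 from 158 ± 1.51 to 24 ± 1.04. Of 16 p53 target genes, 13 were higher and 3 lower (median 0.55, adjusted p = 0.00413), with the cell cycle inhibitor gene Cdkn1a at 74.5 ± 1.7 in WT and 319 ± 4.9 in KO.

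These 6 calls at day 0 hold when the correlation between a list's genes is estimated, and 5 others do not. Of 25 extracellular matrix genes, 20 were higher and 4 lower (median 1.31, adjusted p = 8.38e-06; adjusted p = 0.133 with an estimated correlation), among them Sparc (1590 ± 15 to 5650 ± 41) and the protease gene Mmp2 (280 ± 6.5 to 3320 ± 36). Of 17 genes of fatty acid synthesis, 12 were lower and 4 higher (median -1.21, adjusted p = 0.0107; adjusted p = 0.13 with an estimated correlation), with the desaturase gene Scd1 at 50.6 ± 0.343 in WT and 14 ± 0.239 in KO. Of 25 oxidative phosphorylation genes, 20 were lower and 1 higher (median -0.45, adjusted p = 0.00114; adjusted p = 0.291 with an estimated correlation). Of 30 ribosomal protein genes, 27 were lower and 0 higher (median -0.69, adjusted p = 1.03e-05; adjusted p = 0.295 with an estimated correlation). After quantile normalization these 2 medians are -0.29 and -0.41, and both lists stay called. The adipocyte genes were not called at this day, with 9 higher and 5 lower of 25 (median 0.13, adjusted p = 0.209).

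The series is about RNA methylation at N6 of adenosine (m6A), so its machinery was a list of its own. At day 0, 19 of 21 m6A genes were lower and 1 higher in KO (median -0.55, adjusted p = 0.00291; adjusted p = 0.124 with an estimated correlation). The methyltransferase gene Mettl3 was at 22.7 ± 0.533 in WT and 14.2 ± 0.346 in KO (log2 change -0.64, SE 0.04, adjusted p = 2.78e-08), its partner Mettl14 at 8.01 ± 0.643 and 5.79 ± 0.223, and the adaptor gene Wtap at 50.5 ± 3.96 and 35.2 ± 0.983. The reader gene Ythdf2 was at 32.3 ± 1.21 in WT and 15.9 ± 0.869 in KO. The demethylase gene Fto was the exception, at 22 ± 1 in WT and 55.2 ± 0.816 in KO, 2.51-fold higher (log2 change 1.29, SE 0.03, adjusted p = 4.03e-12). Fto lies on chromosome 8, where the median change of 682 genes lay above that of all genes by 0.42 at day 0 and 0.40 at day 2 in log2. The other demethylase gene, Alkbh5, was at 43.6 ± 1.13 in WT and 43.4 ± 1.01 in KO (adjusted p = 0.839), and the sign of this small difference turns with TPM, median-of-ratios and quantile scaling.

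Among adipogenic transcription factors at day 0, Pparg, the master regulator of fat cell formation, was at 10.2 ± 0.466 in WT and 2.85 ± 0.596 in KO (log2 change -1.55, SE 0.09, adjusted p = 6.69e-09). Pparg lies on chromosome 6, where the median change of 602 genes departed from that of all genes by -0.34 at day 0 and -0.31 at day 2. Cebpb went from 51.7 ± 1.92 to 36.1 ± 1.56, Cebpd from 20.9 ± 1.81 to 12.5 ± 0.251 and Cebpa from 3.63 ± 0.183 to 4.61 ± 0.444, all past the threshold. The list as a whole was not called, with 9 higher and 8 lower of 19 (median 0.14, adjusted p = 0.609). The fat cell genes Fabp4 (1.18 ± 0.132 in WT, 1.96 ± 1.39 in KO, adjusted p = 0.166, log2 change 0.35, which is -0.01 without KO day 0 replicate 1 and passes at 0.56 without KO day 0 replicate 2) and Adipoq (0.052 ± 0.0514 in WT, 0.0572 ± 0.0607 in KO, adjusted p = 0.932) were near the floor in both genotypes. TPM scaling moves the median of all genes in this comparison by 0.10 in log2. Counts adjusted over the list alone were the same as those over all genes except in 1 list, where they differed by 1 gene.

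At day 2 the comparison of KO with WT asks how far the labelled knockout cells differ at day 2 of the cocktail. The fat cell genes differed most. Fabp4, the fatty acid carrier of adipocytes, was at 2970 ± 79.2 in WT and 10.3 ± 0.367 in KO (log2 change -8.04, SE 0.22, adjusted p = 8.18e-12). The lipid droplet coat gene Plin1 was at 522 ± 5.88 in WT and 7.67 ± 0.261 in KO, 68.1-fold lower, and the adiponectin gene Adipoq at 47.1 ± 0.834 and 0.472 ± 0.0583. The collagen gene Col1a1 was higher in KO, at 161 ± 2.2 in WT and 2020 ± 40 in KO. Of 12961 genes 10551 passed, 5294 higher and 5257 lower, and 1671 and 1485 of these differed at least 2-fold. Falls outnumber rises with a minimum of 5 FPKM (4015 higher, 4347 lower), after median-of-ratios scaling (5185 and 5351) or quantile normalization (5091 and 5392), with only the libraries compared (5199 and 5220) and without KO day 2 replicate 1 (5156 and 5157).

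The largest falls at day 2 were those of Fabp4, the fatty acid receptor gene Cd36 (640 ± 10.2 to 2.91 ± 0.257), the lipolysis inhibitor gene G0s2 (179 ± 0.546 to 0.11 ± 0.05), Plin1, the melanocortin receptor accessory gene Mrap (59 ± 1.4 to 0.29 ± 0.0514, 204-fold) and the resistin gene Retn (102 ± 3.37 to 1.32 ± 0.196, 77.5-fold). The largest rises were those of the imprinted gene Ndn (3.93 ± 0.194 to 360 ± 3.3, 91.7-fold), the neuropeptide Y receptor gene Npy1r (0.397 ± 0.109 to 54.5 ± 0.768, 137-fold), Serpinb7 (0.0286 ± 0.0495 to 36.4 ± 2.06), Slc4a10 (0.0932 ± 0.0645 to 35.6 ± 0.422), the cadherin gene Cdh13 (6.53 ± 0.169 to 211 ± 2.93, 32.4-fold) and the matrix gene Ecm1 (51 ± 1 to 1320 ± 22.2, 25.9-fold). The adjusted p of these 12 genes was at most 8.18e-12.

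By list, 24 of 25 adipocyte genes were lower in KO at day 2 and 1 was higher (median -3.48, adjusted p = 5.85e-10). The gene that was higher was Orm1, an acute phase gene, at 5.93 ± 0.65 in WT and 24 ± 0.39 in KO. The fatty acid carrier gene Fabp5 went from 1180 ± 35.8 to 38.9 ± 2.87 and the lipoprotein lipase gene Lpl from 2420 ± 12.6 to 273 ± 6.56. All 24 mitotic genes were lower (median -1.92, adjusted p = 2.03e-09), as were 25 of 26 DNA replication genes, with 1 higher (median -1.18, adjusted p = 8.61e-07). The gene that was higher was Pcna, at 207 ± 1.6 in WT and 417 ± 12 in KO. Of 26 interferon-stimulated genes 22 were higher and 1 lower (median 0.85, adjusted p = 6.61e-04). Of 15 inflammatory genes 12 were higher and 3 lower (median 1.44, adjusted p = 0.00301), such as the chemokine gene Ccl7 (2.08 ± 0.17 to 46.8 ± 2.4) and the prostaglandin synthase gene Ptgs2 (1.6 ± 0.25 to 22.5 ± 0.5). These 5 calls hold with an estimated correlation.

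Of the lists at day 2, 10 more were called with the preset correlation only. All 25 oxidative phosphorylation genes were lower (median -1.30, adjusted p = 1.43e-09; adjusted p = 0.0564 with an estimated correlation), with the cytochrome c gene Cycs at 946 ± 9.84 in WT and 58.5 ± 4.97 in KO. Of 10 preadipocyte markers 8 were higher and 1 lower (median 2.11, adjusted p = 0.00857; adjusted p = 0.0564 with an estimated correlation), such as Thy1 (32 ± 0.702 to 298 ± 6.96), Pdgfra (37.9 ± 1.65 to 177 ± 2.82) and Dlk1 (68.7 ± 1.22 to 301 ± 3.55). Of 25 matrix genes 21 were higher and 3 lower (median 1.88, adjusted p = 6.82e-07; adjusted p = 0.067 with an estimated correlation). Cholesterol synthesis genes were lower in 16 and higher in 5 of 21 (median -0.67, adjusted p = 0.00607), contractile genes higher in 9 and lower in 2 of 14 (median 0.35, adjusted p = 0.0297), cyclic AMP and immediate early genes higher in 11 and lower in 3 of 16 (median 0.66, adjusted p = 0.0297), and p53 targets higher in 12 and lower in 3 of 16 (median 0.48, adjusted p = 0.0297). For each of these 4 lists the adjusted p = 0.067 with an estimated correlation. Examples are Cald1, which binds actin (85.2 ± 2.48 to 354 ± 5.81), the orphan receptor gene Nr4a1 (20.3 ± 0.822 to 69.9 ± 1.64) and the receptor gene Eda2r (3.84 ± 0.23 to 57.6 ± 0.9).

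Fatty acid synthesis genes at day 2 were lower in 11 and higher in 4 of 17 (median -0.73, adjusted p = 0.0336; adjusted p = 0.137 with an estimated correlation), with Scd1 at 541 ± 4.12 in WT and 54.2 ± 0.732 in KO. All 4 thermogenic genes tested were lower (median -1.29, adjusted p = 0.0338; adjusted p = 0.0931 with an estimated correlation), while Ucp1, which defines the brown fat cell, is listed at 0 in all 4 groups. Of the 12 listed, 4 reached the minimum mean over all libraries, which a gene high in WT day 2 alone can reach. Such a gene is lower in KO at day 2 and rises in WT. These directions, and that of the interaction, can thus follow in part from the filter. All 3 chondrocyte markers tested were higher (median 1.57, adjusted p = 0.0336; adjusted p = 0.137 with an estimated correlation), with the matrix gene Comp at 2.03 ± 0.159 in WT and 7.64 ± 1.32 in KO. Ribosomal protein genes were not called, with 15 higher and 9 lower of 30 (median 0.09, adjusted p = 0.298). Quantile normalization ends the calls of the fatty acid (median -0.64) and contractile (0.22) lists, and a minimum of 5 FPKM that of the fatty acid list (-0.64). The thermogenic difference was larger but no longer called with a pseudocount of 0.1 (-1.89) and in the fit on recovered reads (-1.95), and its median is near 0 with no filter, where members close to the floor enter. The contractile median was 0.67 with a pseudocount of 0.1, 0.75 with a minimum of 5 FPKM and 0.91 in the fit on recovered reads, and that of the interferon list 1.77 with a pseudocount of 0.1 and 2.60 in that fit, all still called. Counts adjusted over the list alone differed from those over all genes in 2 lists, by 1 gene each.

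The regulators split at day 2. Pparg was at 150 ± 4 in WT and 33.7 ± 1 in KO (log2 change -2.12, SE 0.09, adjusted p = 3.21e-10) and Cebpa at 186 ± 5.93 and 31.1 ± 1.21 (log2 change -2.54, SE 0.06, adjusted p = 1.19e-12). Cebpd, an early factor, was higher, at 57.1 ± 1.2 in WT and 222 ± 13.2 in KO (adjusted p = 1.25e-11). Cebpb, its partner, was at 262 ± 12.3 in WT and 257 ± 28.7 in KO (adjusted p = 0.643), a difference whose sign turns with TPM and quantile scaling and without WT day 2 replicate 2 or KO day 2 replicate 3, and which passes at -0.12 without KO day 2 replicate 1. The list of adipogenic factors was not called, with 9 higher and 7 lower of 19 (median 0.05, adjusted p = 0.681). Of the m6A genes 13 were lower and 5 higher (median -0.21, adjusted p = 0.211). Mettl3 was at 18 ± 0.557 in WT and 13.5 ± 0.759 in KO, Mettl14 at 7.11 ± 0.135 and 3.99 ± 0.261, Wtap at 39.6 ± 0.493 and 33.2 ± 0.284, and Fto at 23.6 ± 0.288 and 36.1 ± 0.57, all past the threshold. Alkbh5 was higher in KO (29.5 ± 1.2 to 37.9 ± 0.43, adjusted p = 7.45e-07). Ythdf2 was at 24.5 ± 0.94 in WT and 21.6 ± 1.52 in KO (log2 change -0.18, SE 0.06, adjusted p = 0.0103), a call that TPM scaling ends.

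The differences between genotypes at the 2 days were compared gene by gene. Among genes past the threshold and at least 2-fold different, 656 were higher at both days, against 173.4 if the days were independent, and 608 were lower at both, against 177.1. Another 119 went opposite ways, against 353.4. Across genes the log2 changes had a Pearson's r of 0.512, where genes are not independent replicates. Serpinb7 and Slc4a10 were among the largest rises at each day.

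**Figure D2:**
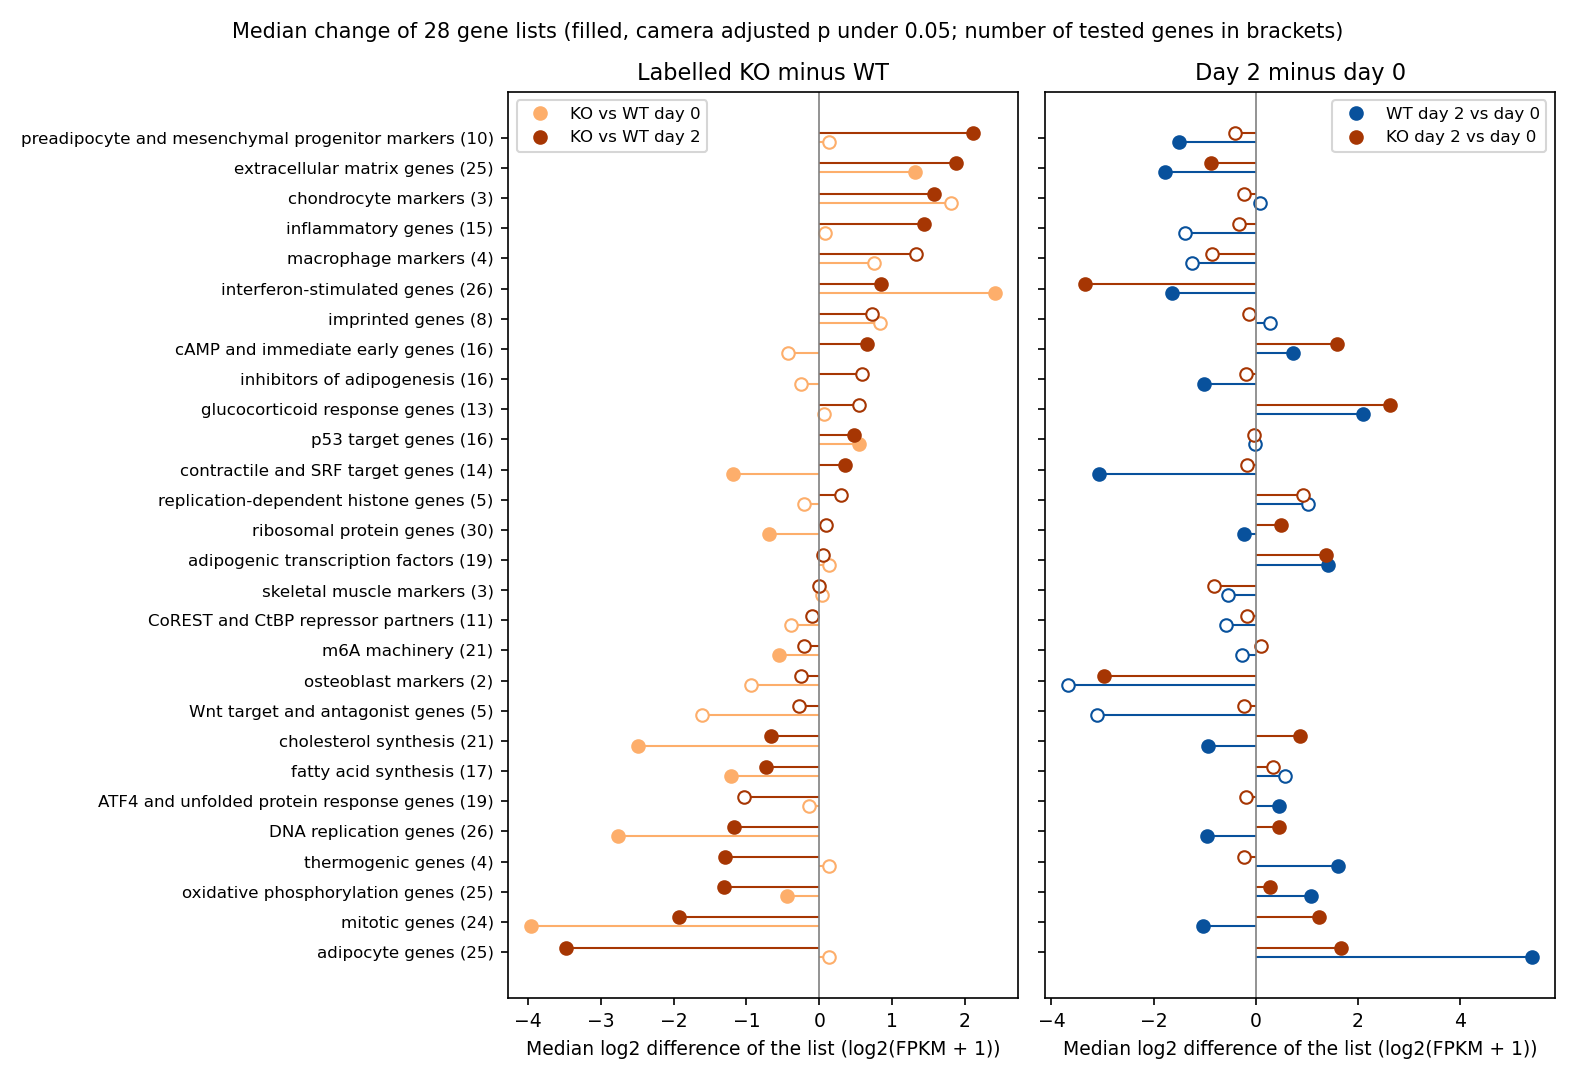
Median log2 change of the genes of each list, KO against WT at both days on the left and day 2 against day 0 in each genotype on the right, in log2 units; filled points passed camera. Mitotic genes are lower in KO at both days (-3.95 and -1.92), while the adipocyte genes differ at day 2 (-3.48) and rise less in KO (1.67) than in WT (5.40).

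The comparison of day 2 with day 0 in WT asks what changed in the cells with that label, where treatment and time go together because no untreated group was taken at day 2. The largest rises were those of fat cell genes. Fabp4 went from 1.18 ± 0.132 to 2970 ± 79.2 (log2 change 10.41, SE 0.22, adjusted p = 6.49e-13), the lipid droplet gene Cidec from 0.659 ± 0.168 to 1520 ± 29.8, Cd36 from 0.22 ± 0.0288 to 640 ± 10.2 and Plin1 from 0.196 ± 0.0833 to 522 ± 5.88. Contractile genes fell, with Acta2 at 541 ± 8.3 at day 0 and 2.54 ± 0.277 at day 2, 213-fold lower. Of 12961 genes 10461 passed, 4429 higher and 6032 lower at day 2, and 1203 and 1953 of these differed at least 2-fold. Quantile normalization ends the excess of falls, with 5226 higher and 5136 lower. The other largest rises were those of G0s2 (0.0364 ± 0.0316 to 179 ± 0.546) and Fam83a (0.176 ± 0.0692 to 193 ± 2.1), and the other largest falls those of the interleukin-33 receptor gene Il1rl1 (108 ± 0.349 to 0.605 ± 0.0926), the annexin gene Anxa3 (255 ± 2.55 to 3.22 ± 0.407), the podoplanin gene Pdpn (131 ± 2.8 to 1.26 ± 0.137), the chemokine gene Ccl2 (93.6 ± 2.4 to 0.851 ± 0.493) and the osteopontin gene Spp1 (524 ± 11.3 to 9.55 ± 0.261). Zfp217 fell from 21.96 ± 0.279 to 15.06 ± 0.369 (log2 change -0.52, SE 0.04, adjusted p = 4.8e-08).

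All 25 adipocyte genes rose in WT (median 5.40, adjusted p = 6.14e-16), such as Acsl1, which activates fatty acids (19.1 ± 0.791 to 2510 ± 14.8, 131-fold), Lpl (55.9 ± 2.32 to 2420 ± 12.6) and the lipase gene Lipe (4.09 ± 0.072 to 340 ± 7.04). All 25 oxidative phosphorylation genes rose (median 1.08, adjusted p = 3.85e-11), such as Uqcrc2 (102 ± 2.42 to 303 ± 3.34). All 13 glucocorticoid response genes rose (median 2.09, adjusted p = 5.5e-07), among them Fkbp5 (36 ± 0.678 to 776 ± 4.74) and Pdk4 (7.22 ± 0.133 to 131 ± 3.18). Of 19 adipogenic factors 16 rose and 3 fell (median 1.41, adjusted p = 3.35e-05), with Cebpa at 3.63 ± 0.183 and then 186 ± 5.93. Lower were 23 of 24 mitotic genes, with 1 higher (median -1.02, adjusted p = 6.74e-05), 24 of 26 DNA replication genes, with 1 higher (median -0.95, adjusted p = 2.83e-05), 13 of 14 contractile genes, with 1 higher (median -3.07, adjusted p = 3.76e-05), and 24 of 26 interferon-stimulated genes, with 1 higher (median -1.64, adjusted p = 1.91e-05). Examples are Foxm1, a regulator of mitotic genes (66.2 ± 2 to 19.3 ± 1.1), the tropomyosin gene Tpm1 (454 ± 4.45 to 40.3 ± 1.05) and Oasl2 (11.7 ± 0.291 to 0.126 ± 0.0626). These 8 calls hold with an estimated correlation.

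A further 8 lists were called in WT with the preset correlation only. Preadipocyte markers fell in 9 and rose in 1 of 10 (median -1.51, adjusted p = 0.0108; adjusted p = 0.0517 with an estimated correlation), such as Thy1 (519 ± 9.8 to 32 ± 0.702) and Pdgfrb (71.4 ± 0.902 to 3.15 ± 0.103). Matrix genes fell in 20 and rose in 5 of 25 (median -1.77, adjusted p = 0.00239; adjusted p = 0.183 with an estimated correlation), and the 3 collagen VI genes were among those that rose, with Col6a3 at 116 ± 0.81 and then 823 ± 12. Inhibitors of adipogenesis fell in 13 and rose in 3 of 16 (median -1.02, adjusted p = 0.0334; adjusted p = 0.136 with an estimated correlation), with Dlk1 at 416 ± 10.1 and then 68.7 ± 1.22. Cholesterol synthesis genes fell in 15 and rose in 4 of 21 (median -0.93, adjusted p = 0.0334; adjusted p = 0.138 with an estimated correlation). Ribosomal protein genes fell in 22 and rose in 1 of 30 (median -0.22, adjusted p = 0.0317; adjusted p = 0.505 with an estimated correlation). Rising were 12 of 19 genes of the ATF4 and unfolded protein response, with 6 falling (median 0.45, adjusted p = 0.0141; adjusted p = 0.136 with an estimated correlation), and all 4 thermogenic genes tested (median 1.61, adjusted p = 0.0171; adjusted p = 0.0734 with an estimated correlation). Cyclic AMP and immediate early genes rose in 10 and fell in 5 of 16 (median 0.73, adjusted p = 0.0486; adjusted p = 0.117 with an estimated correlation). Quantile normalization moves the median of all genes by 0.16 in log2 in this comparison and the fit on recovered reads by 0.11. The call of the cyclic AMP list ends with each change of scaling, a pseudocount of 0.1, no variance trend, the fit on recovered reads, and without WT day 2 replicate 2 (median 0.75), WT day 2 replicate 3 (0.72) or KO day 0 replicate 3 (0.73). That of the ribosomal list ends with median-of-ratios (-0.12) or quantile (-0.16) scaling, the fit on recovered reads (-0.11) and without WT day 2 replicate 3 (-0.22), that of the ATF4 list with quantile normalization (0.45), and that of the inhibitors with a minimum of 5 FPKM (-0.94).

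Some medians of the WT lists depend on how low values are handled, while the lists stay called. That of the preadipocyte markers was -2.62 with a pseudocount of 0.1, -2.78 in the fit on recovered reads and -3.72 with a minimum of 5 FPKM, where 5 of the 10 genes remain. That of the interferon-stimulated genes was -3.50 with a pseudocount of 0.1 and -4.23 in the fit on recovered reads. That of the thermogenic genes was 2.44 in the same fit and 0.11 with no filter, and that of the cyclic AMP list 0.46 with no filter. Counts adjusted over the list alone were the same as those over all genes in all 28 lists.

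In the KO-labelled cells, whose Zfp217 message went from 25.97 ± 0.883 to 22.59 ± 0.858 (log2 change -0.19, SE 0.04, adjusted p = 4.36e-04), other genes rose and fell most. The eosinophil-associated ribonuclease gene Ear2 went from 8.62 ± 1.59 to 3380 ± 218, with its close paralogs Ear1 (0.88 ± 0.317 to 282 ± 46.5) and Ear10 (2.54 ± 0.425 to 312 ± 12.1), between which reads cannot always be told apart. The acute phase gene Orm3 went from 0.479 ± 0.169 to 176 ± 4.52. Interferon-stimulated genes fell most, with Ifit3 at 61.9 ± 1.56 and then 0.438 ± 0.094, Oasl2 at 90.3 ± 1.9 and then 1.28 ± 0.153, and Isg15 at 155 ± 1.48 and then 3.2 ± 0.498. Hsp90aa1 went from 177 ± 2.35 to 6.18 ± 1.5 (log2 change -4.65, SE 1.00, adjusted p = 0.00123), which the fit on recovered reads no longer calls at a similar size (-4.84), and it followed the mitochondrial ribosomal RNAs across libraries, as given above. Of 12961 genes 9426 passed, 4397 higher and 5029 lower, and 708 and 906 of these differed at least 2-fold. The excess of falls turns after median-of-ratios scaling (4934 higher, 4486 lower), quantile normalization (4774 and 4707) and in the fit on recovered reads (4805 and 4570).

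Of 25 adipocyte genes 21 rose and 1 fell in KO (median 1.67, adjusted p = 1.5e-09), with Acsl1 at 12.6 ± 0.567 and then 209 ± 5.96 and Pnpla2, the first lipase of fat breakdown, at 22.6 ± 0.423 and then 419 ± 2. Of 19 adipogenic factors 11 rose and 6 fell (median 1.38, adjusted p = 0.00228), with the early factor gene Klf5 at 0.729 ± 0.0702 and then 31.7 ± 0.227. All 13 glucocorticoid response genes rose (median 2.63, adjusted p = 8.33e-10), such as Errfi1 (7.07 ± 0.359 to 312 ± 3.26) and Tsc22d3 (29.4 ± 1.06 to 637 ± 14.3). Cyclic AMP and immediate early genes rose in 11 and fell in 5 of 16 (median 1.59, adjusted p = 0.00239), such as Nr4a1 (3.32 ± 0.264 to 69.9 ± 1.64). All 24 mitotic genes rose (median 1.24, adjusted p = 5.89e-11), as did 23 of 26 DNA replication genes, with 2 falling (median 0.45, adjusted p = 1.02e-05), and 20 of 21 cholesterol synthesis genes, with 0 falling (median 0.87, adjusted p = 6.92e-09). The topoisomerase gene Top2a went from 11.2 ± 0.091 to 108 ± 2. All 26 interferon-stimulated genes fell (median -3.33, adjusted p = 3.91e-13). These 8 calls hold with an estimated correlation.

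The other 4 lists called in KO depend on the preset correlation. Ribosomal protein genes rose in 28 and fell in 0 of 30 (median 0.50, adjusted p = 2.1e-08; adjusted p = 0.192 with an estimated correlation). Oxidative phosphorylation genes rose in 16 and fell in 2 of 25 (median 0.28, adjusted p = 0.00228; adjusted p = 0.257 with an estimated correlation), and matrix genes fell in 19 and rose in 5 of 25 (median -0.87, adjusted p = 7.15e-05; adjusted p = 0.167 with an estimated correlation). Both osteoblast markers tested fell (median -2.98, adjusted p = 0.0265; adjusted p = 0.107 with an estimated correlation), which are Runx2 (25.1 ± 0.87 to 7.34 ± 0.45) and Spp1 (209 ± 2.5 to 9.67 ± 1.1). The call ends with TPM (median -1.35) and median-of-ratios scaling (-1.59), where Alpl, and with TPM also Phex, pass the minimum level and the list grows to 4 and 3 genes. With no filter the median is -0.27, and the list stays called. Other medians of called lists that moved by more than 1.5 times were those of the adipocyte genes in the fit on recovered reads (2.81) and, after quantile normalization, of the oxidative phosphorylation (0.13) and ribosomal (0.29) genes. Counts adjusted over the list alone differed from those over all genes in 3 lists, by 1 gene each.

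**Figure D3:**
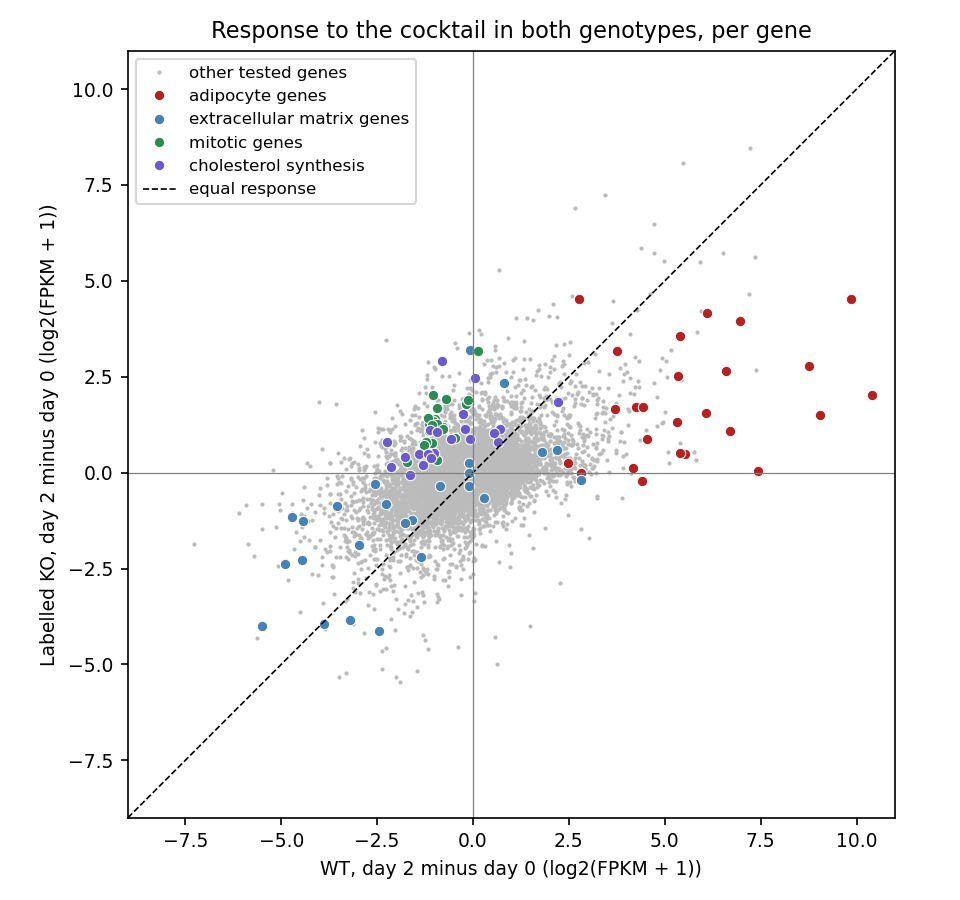
Log2 change from day 0 to day 2 in KO against that in WT, for each gene, in log2 units, with 4 gene lists in colour and a dashed line of equal change. Across genes r was 0.513, and 24 of the 25 adipocyte genes lie below the line, with a median of 1.67 in KO and 5.40 in WT.

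The interaction asks whether the change from day 0 to day 2 differed between the genotypes, as the KO change minus the WT change. Fat cell genes rose less in KO, by -8.39 in log2 for Fabp4 (SE 0.31, adjusted p = 2.76e-10), -7.54 for Cd36 (SE 0.11), -7.39 for G0s2 (SE 0.08) and -5.99 for Plin1 (SE 0.08). The largest positive values were those of the protease inhibitor gene Slpi (5.85, SE 0.19), the vitamin D receptor gene Vdr (5.72, SE 0.07), Acta2 (5.40, SE 0.07) and the matricellular gene Ccn1 (5.35, SE 0.07). Acta2 fell in both genotypes, from 541 ± 8.3 to 2.54 ± 0.277 in WT and from 74 ± 1.21 to 19.6 ± 1.1 in KO. The adjusted p of these 8 genes was at most 2.76e-10. Of 12961 genes 9560 passed, 5282 positive and 4278 negative, and 1655 and 1129 of these were at least 2-fold. Quantile normalization turns this balance, with 4636 positive and 4919 negative.

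By list, the difference was negative for 24 and positive for 1 of 25 adipocyte genes (median -3.94, adjusted p = 1.69e-13) and negative for 24 and positive for 0 of 25 oxidative phosphorylation genes (median -0.95, adjusted p = 3.9e-10). The difference was positive for all 24 mitotic genes (median 2.2, adjusted p = 1.94e-10), for 25 of 26 DNA replication genes, with 0 negative (median 1.54, adjusted p = 6.05e-09), for 19 of 21 cholesterol synthesis genes, with 1 negative (median 1.58, adjusted p = 8.52e-08), for 13 of 14 contractile genes, with 1 negative (median 2.50, adjusted p = 9.12e-06), and for 9 of 10 preadipocyte markers, with 1 negative (median 1.81, adjusted p = 0.00322). Mki67, for example, fell in WT from 53.7 ± 3.1 to 24.3 ± 0.28 and rose in KO from 1.81 ± 0.13 to 5.49 ± 0.37. These 7 calls hold with an estimated correlation.

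For the interferon-stimulated genes the difference was negative for 22 and positive for 2 of 26 (median -1.68, adjusted p = 4.42e-07; adjusted p = 0.0055 with an estimated correlation), but it depends on how values near the floor are handled. At day 2, 16 of the 26 genes had a mean under 1 FPKM in WT and 7 in KO, where the pseudocount of 1 shrinks a fall. The median was -0.76 with a pseudocount of 0.1 and -0.15 in the fit on recovered reads, where the list was no longer called. In that fit Mx1 went from -2.43 to 1.60 and Oas2 from -2.94 to -0.33.

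The remaining 6 interaction calls do not hold with an estimated correlation. They are the ribosomal protein genes (28 positive and 0 negative of 30, median 0.73, adjusted p = 5.35e-07; adjusted p = 0.209 with an estimated correlation), the thermogenic genes (0 and 4 of 4, median -1.99, adjusted p = 0.0142; adjusted p = 0.0607 with an estimated correlation) and the cyclic AMP and immediate early genes (12 and 4 of 16, median 1.07, adjusted p = 0.0204; adjusted p = 0.0607 with an estimated correlation). The inhibitors of adipogenesis (11 and 2 of 16, median 0.88; adjusted p = 0.152 with an estimated correlation), the inflammatory genes (10 and 4 of 15, median 1.39; adjusted p = 0.0886 with an estimated correlation) and the ATF4 and unfolded protein response genes (5 and 13 of 19, median -0.38; adjusted p = 0.197 with an estimated correlation) each had an adjusted p = 0.04 with the preset correlation, and quantile normalization ends the last of these calls (-0.40). With no filter the medians are -0.32 for the thermogenic and 1.28 for the contractile genes, with a minimum of 5 FPKM 2.19 for the inflammatory genes, after quantile normalization 0.45 for the ribosomal genes and in the fit on recovered reads -2.98 for the thermogenic genes, all still called. Sox9, an inhibitor of fat cell formation, fell in WT from 26.5 ± 1.22 to 4.9 ± 0.188 and rose in KO from 14.7 ± 0.89 to 24.3 ± 0.396. Counts adjusted over the list alone differed from those over all genes in 5 lists, by 1 gene each.

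The size of the response was compared for the 1942 genes whose change averaged over both genotypes passed the threshold and was at least 2-fold, a choice that favours neither genotype. Of these 1425 responded less in KO, a share of 73.38%. The median ratio of the log2 change in KO to that in WT was 0.5632, with opposite directions counted as negative. The median size was 1.96 in log2 in WT and 1.14 in KO, and 87 genes went opposite ways. Among genes past the threshold and at least 2-fold changed in both genotypes, 328 rose in both, against 65.7 if the genotypes were independent, 566 fell in both, against 136.5, and 86 went opposite ways, against 190.8. This share describes the values and has no test that can exclude chance.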

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

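The tests on Zfp217, on chromosomes 8 and 6 and on the mitotic genes, and the regroupings without the average genotype difference, were chosen after those results were seen, and the other regroupings before.

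Changes from day 0 to day 2 differed between the genotypes by the interaction test. For 9560 of 12961 genes the difference passed. The lists that differed had median differences in log2 of -3.94 for adipocyte genes, 1.58 for cholesterol synthesis, 0.88 for inhibitors of adipogenesis, 1.81 for preadipocyte markers, 2.2 for mitotic genes, 1.54 for DNA replication, 2.50 for contractile genes, 1.07 for cyclic AMP and immediate early genes, -1.68 for interferon-stimulated genes (-0.15 and not called in the fit on recovered reads), 1.39 for inflammatory genes, -0.38 for the ATF4 and unfolded protein response, -0.95 for oxidative phosphorylation, -1.99 for thermogenic genes and 0.73 for ribosomal protein genes. With an estimated correlation 6 of these lose their call, namely the inhibitors, the cyclic AMP, inflammatory, ATF4, thermogenic and ribosomal lists (adjusted p from 0.0607 to 0.209). Single genes that differed were Zfp217 (0.32), Slpi (5.85), Vdr (5.72), Acta2 (5.40), Ccn1 (5.35), Fabp4 (-8.39), Cd36 (-7.54), G0s2 (-7.39) and Plin1 (-5.99). Of 177 gene names picked by the naming rule in the other comparisons, 168 passed for the interaction. Most of these names were picked for large or clear changes in the same libraries, and 73.8% of all tested genes passed. A high share was therefore built in.

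Genotype labels were regrouped within each day to give 100 splits, the real one included. In only 1 split, the real one, did 9560 genes pass for the interaction, and the highest of the others gave 5217. Likewise 1 of 100 gave 14 lists, with 12 as the highest other, but since most splits mix the genotypes, this shows that the libraries group by genotype and not that the changes differ. With the average genotype difference of each gene taken out first, 1 of 100 splits, the real one, gave 9560 genes. The highest other gave 1 gene. For lists 1 of 100 gave 14 and the highest other 13, a margin of 1 list that is too thin to decide. The real labels thus stand apart for the gene count. A mixed split, however, pools libraries that still differ by the interaction, which widens its spread and lowers its count. The libraries of a group can also be technical replicates, so chance between cultures is not excluded. For the share of smaller responses in KO, 28 of 100 splits were as far from equal as the real 73.38%. The other share furthest from equal was 80.57%. With the average genotype difference taken out, 40 of 100 were as far, and the other share furthest from equal was 25.35%. Chance is not excluded, but the counts cannot measure it either, since a mixed split keeps a part of the real difference or cancels it, and a share does not depend on the size of that part. For comparisons of 3 libraries with 3, only 10 splits exist, too few for a share below the threshold. Fits of the 6 libraries gave 10670, 10419, 10411 and 9209 genes for KO with WT at day 0 and day 2 and for the response in WT and KO, each in 1 of 10 splits, with 0 genes as the highest other. Every other split mixes the groups compared, which widens its spread and lowers its count, so these low counts do not measure chance. For lists the real counts were 11, 15, 15 and 13 and the highest others 11, 10, 12 and 11, with 5 of 10 splits as high at day 0 and 1 of 10 in the rest.

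The Zfp217 message was higher where the label says knockout. Scaling is argued against, since the lowest log2 change over 4 other scalings and both days was 0.255. Extra copies of a region reaching 2 Mb to each side are argued against as well, since the 7 expressed genes within 2 Mb had medians of -0.44 at day 0 and -0.40 at day 2. Of these, 0 passed the threshold as higher at both days and 4 as lower at both. Expression does not measure copy number, and a gain of a narrower stretch at Zfp217 was not tested and stays open. Labels exchanged at a single day would make the differences of the 2 days oppose each other, but their r across genes was 0.512. An exchange of all labels, or an allele that keeps the message and loses the protein, stays open and cannot be tested with gene-level values.

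Genes of chromosome 8 were on the whole higher and those of chromosome 6 lower in KO at both days, with departures from the median of all genes of 0.42 and 0.40, and of -0.34 and -0.31. The change from day 0 to day 2 showed no such departure (-0.01 in WT and 0.03 in KO for chromosome 8). A random spread of genes over chromosomes is argued against, since a share of 0.0001 of 10000 reassignments, the smallest they can give, had a departure as large, the highest other being 0.154. Chromosomes 12 (-0.20 and -0.31), 15 (0.17 and 0.19) and 2, which holds Zfp217 (-0.16 and -0.23), passed that value at both days as well, so the pattern is not particular to 8 and 6. A gain or loss of whole chromosomes may account for it: a first test, on the departure of 0.40 alone, had come out for it and was replaced after that was seen. In the test by blocks of 10 Mb that took its place, 22 of 28 blocks moved with their chromosome, or 78.6%, just under the share that test required. Whole chromosomes therefore cannot be told apart from smaller segments or from regulation, and how much of the difference in Fto and Pparg comes with their chromosome is open.

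Mitotic genes were lower in KO at day 0. Scaling is argued against, since the highest median over 4 other scalings was -3.92. A growth state that differed at day 0 and was gone by day 2 is argued against as the whole account, since the median at day 2 was -1.92. That median was nearer to 0 than at day 0 (-3.95). A state such as earlier confluence can carry over to day 2, so the test cannot speak to it. A lasting difference in proliferation between the cultures, whether from the genotype or from the history of a clone, stays open and untested.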

How the results depend on the processing

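Of the alternatives for the comparisons, 280 values were kept and 24 counts moved by more than 1.5 times. A count was kept if its total stayed within 1.5 times, whatever its split between directions, which turned in some settings as given above. For Zfp217 only the sign and the call were checked. For KO with WT at day 0 and day 2, the WT response, the KO response and the interaction, a 2-fold minimum gave 2891, 3156, 3156, 1614 and 2784 genes, and the treat test at 1.5-fold, chosen after seeing the data, 4350, 4599, 4452, 2363 and 3700, fewer since each asks for a minimum size. Camera with an estimated correlation called 6, 5, 8 and 8 lists at day 0, day 2, in WT and in the interaction. Fry, which tests no list against other genes, called 27, 27, 28, 28 and 27 lists in 1 direction and 28, 26, 28, 28 and 27 in either. With a replicate block the gene counts were 10652, 10515, 10411, 9386 and 9486. Leaving out single libraries gave 10388 to 10737, 10275 to 10540, 10161 to 10483, 9034 to 9408 and 9318 to 9401 genes, lists from 11 to 11, 15 to 15, 14 to 17, 12 to 13 and 14 to 15, a share of smaller responses from 72.91 to 74.02%, and Zfp217 changes of 0.206 to 0.253 at day 0 and 0.53 to 0.582 at day 2. For single genes 7186 values kept their call, 3 lost it, 2 gained it and 15 changed sign, and for lists 1504 kept it and 57 lost it, the cause of which was not tested. Alkbh5 at day 0 was 0.097 with TPM, 0.016 with median-of-ratios, 0.132 with quantile scaling, 0.078 with voom, and -0.027 to 0.011 with single libraries left out. Fabp4 at day 0 ran from -0.014 to 0.556 with single libraries left out. Adipoq at day 0 was -0.026 with quantile scaling and -0.036 to 0.046 with single libraries left out. Cebpb at day 2 was 0.01 with TPM, 0.226 with quantile scaling and -0.123 to 0.029 with single libraries left out. None of these 4 genes had passed there. The interaction of Mx1, which had passed at -2.43, was 1.602 with voom, also chosen after seeing the data, and -1 with a pseudocount of 0.1. Counting noise weighs most on genes near the floor, such as Adipoq at day 0.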

Other observations

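Some genes were expressed in 1 genotype alone at both days. Of 8640 genes at 5 FPKM or more in WT at both days, 2 were at 2% of that or less in KO, Ctsz and Rhox5. Rhox5, a homeobox gene of the X chromosome, was at 20.25 ± 0.629 and 18.71 ± 0.127 in WT at day 0 and day 2 and at 0.2828 ± 0.11 and 0.09302 ± 0.0403 in KO (SD, n = 3). In the other direction 11 of 8851 genes were near the floor in WT. Among them were Igfbp5, which binds insulin-like growth factors (0 and 0.003152 in WT, 9.688 ± 0.368 and 15.63 ± 0.251 in KO), the synapse scaffold gene Dlg2 (0.005591 and 0.02251 in WT, 12.33 ± 0.522 and 7.432 ± 0.114 in KO), Hpse2 (0.009127 and 0.01722 in WT, 27.35 ± 0.597 and 8.636 ± 0.199 in KO), Serpinb7, Slc4a10 and Ostn. All were chosen after their values were seen.

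Markers of other cell types were low in some lists and not in others. Of macrophage markers 4 were tested, and 3 were higher and 0 lower in KO at each day (medians 0.76 and 1.33, adjusted p = 0.239 and 0.128). The lysozyme gene Lyz2 was at 1.5 ± 0.24 in WT and 14.8 ± 0.16 in KO at day 0, while the pan-leukocyte gene Ptprc was at 0.0054 and 0.0225 FPKM. No epithelial marker of 10 and 1 endothelial marker of 9, Egfl7, reached the minimum level, and Epcam is listed at 0 in all groups. Of 13 skeletal muscle markers 3 were tested and the list was not called (adjusted p = 0.878 at day 0 and 0.826 at day 2), though the troponin gene Tnnt2 was at 35.5 ± 0.8 in WT and 0.926 ± 0.24 in KO at day 0. Of 8 osteoblast markers the 2 tested were lower in KO at day 0 (adjusted p = 0.209), with Spp1 at 524 ± 11 in WT and 209 ± 2.5 in KO and Runx2 at 37.1 ± 0.84 and 25.1 ± 0.87. Of 8 chondrocyte markers the 3 tested were higher in KO at day 2 (adjusted p = 0.0336; adjusted p = 0.137 with an estimated correlation), with Col11a1 at 31.1 ± 0.36 in WT and 94.2 ± 3.8 in KO and Sox9 at 4.9 ± 0.19 and 24.3 ± 0.4.

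Of the lists never called, the CoREST and CtBP partners had 4 genes higher and 7 lower of 11 at day 0 (adjusted p = 0.413) and 5 and 6 at day 2 (adjusted p = 0.681). The Wnt list had 1 higher and 4 lower of 5 at day 0 (adjusted p = 0.214) and at day 2 a negative median (-0.28) with a positive mean (0.12, adjusted p = 0.919). Imprinted genes had 5 higher and 2 lower of 8 at day 0 (adjusted p = 0.0631) and 5 and 3 at day 2 (adjusted p = 0.298), with Ndn at 14.2 ± 0.86 in WT and 195 ± 3 in KO at day 0 and the paternally expressed Peg10 at 25.5 ± 0.42 and 2.63 ± 0.23. Replication-dependent histone genes, a sign of how RNA was selected, had 1 higher and 1 lower of 5 at day 0 (adjusted p = 0.996) and 2 and 2 at day 2 (adjusted p = 0.836).

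The test of a lost stretch was chosen after its result could be seen. A hypothesis was the loss of a stretch of chromosome 2 from Zfp217 to Ctsz, which lies on the same chromosome from 174427494 to 174439039. Against the loss of every copy, 0 of the 16 genes between them at 5 FPKM or more in WT were silent in KO, or 0%. Silent here means 2% of the WT level or less, so a loss of some copies was not tested. Most of the 16 genes were lower in KO at each day and the rest were not, so such a loss stays open. A loss at Ctsz alone stays open. Another hypothesis was that Mdm2 on chromosome 10, the p53 ubiquitin ligase gene, lies in an amplified region reaching 0.5 Mb to each side. It was at 2739 ± 12.1 FPKM in WT and 3071 ± 38.4 in KO at day 0 and at 4274 ± 40.5 and 3519 ± 51.3 at day 2, among the 15 most abundant messages of each group. The 8 other expressed genes within 0.5 Mb had a median abundance percentile of 64, below the bound set for such a region. A rank of expression does not measure copy number, so this cannot exclude a region of that size. The bounds of this test were written before its result, but the claim was narrowed to this size after the value was seen. The adjacent Slc35e3 was at 1644, 1959, 1500 and 1489 FPKM in WT day 0, WT day 2, KO day 0 and KO day 2, so a narrower stretch stays open.

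In WT day 0 replicate 3 the mitochondrial ribosomal RNA mt-Rnr2 was at 277 FPKM, against 5.59 and 6.13 in the other WT day 0 libraries and 367 to 374 in KO day 0. Lars2 was at 99.5 FPKM there, 5.45 and 6.24 in the other WT day 0 libraries and 107 to 122 in KO day 0, and Rpl12 at 1370, 89.3 and 86.2, and 678 to 680. Without this library the KO with WT comparison at day 0 called 10393 genes.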
